A study of Mus musculus with 2 samples.

How the data were processed

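Single cells were measured in 2 libraries of E11.5 left lung lobes of CD1 mice, with cells pooled from 4 lungs in replicate 1 and from 3 in replicate 2. Per the labels' protocols, the lobes were treated with dispase, dissociated by hand and filtered, and the replicates were handled separately. Cells were captured with the 10x Genomics 3' v2 kit and sequenced as paired ends on a HiSeq 2500 in rapid mode. The deposited values were raw UMI counts per gene and barcode, which the authors had not filtered to cells or normalized, per the file headers and the values themselves. Each matrix held 27998 genes and 737280 barcodes. Cell Ranger 2.0.1, Seurat 3 and the mouse build mm10 were named in the submitters' processing notes, and their roles were not given in the sources used here. Gene symbols and identifiers were those of the deposited gene tables, and gene coordinates were taken from the GENCODE annotation of mm10.

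Cells were called from the raw barcodes by the rule of early Cell Ranger versions. A barcode was kept with at least a 1 in 10 part of the UMIs at percentile 99 of the top 3000 barcodes, which came to 3528 UMIs in replicate 1 and 2258 in replicate 2. It also needed 1000 UMIs and under 10% mitochondrial UMIs. This kept 901 and 1082 barcodes by UMIs, and 897 and 1061 under the mitochondrial limit. Scrublet, as in scanpy 1.11.5, with an expected rate of 0.8% per 1000 cells, marked 5 and 2 doublets (0.557% and 0.189%), which were removed. The remaining 892 and 1059 cells held 71.3% and 66.3% of the UMIs. Shares of cells were given with exact Clopper-Pearson 95% intervals, which cover counting error only.

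Each UMI was assigned at random (seed 1, 50%) to a training or a held-out set. Training UMIs clustered and named the cells, and held-out UMIs were summed per library and class and tested, so the counts tested did not shape the clusters. Clustering used the 1000 genes with the highest variance of Pearson residuals (theta 100, seen in at least 1% of cells), 20 principal components, 20 neighbours and Leiden at resolution 1.0, which gave 12 clusters. Genes of the fixed lists, mitochondrial, ribosomal protein and sex-linked genes were left out of these features. A cluster took the class whose markers stood highest in it, with at least 3 markers at 20 CPM or more. Mesenchymal-like cells were clustered again with 500 genes, 10 components and resolution 0.6, scaled within each library, after regression on scores of the G1/S and G2/M lists and without erythroid markers. Of the 5 clusters, 1 held the highest level of at least 3 smooth muscle markers and was called smooth muscle-like. The planned comparison of sub-epithelial-like with sub-mesothelial-like clusters was not possible, because too few sub-mesothelial markers reached 20 CPM in any cluster. Figf stood at most at 7.42 CPM in a cluster of a library, and Fgf10 stood highest in M1, at 20.3 and 19.2 CPM (mean 19.8). Nor did the markers of both positions part the clusters, since the sub-epithelial marker Ptch1 stood at 288 ± 22.8 CPM (mean ± SD) in M3 and 284 ± 77.7 in the smooth muscle-like cluster, and the sub-mesothelial marker Wnt2 at 147 ± 25.5 in M3 and 135 ± 8.51 in M1. Each numbered cluster was compared with the mean of the others in its place. The smooth muscle score was the mean log level (scaled to 10000 UMIs per cell) of the smooth muscle markers in training UMIs, averaged over 30 nearest cells, and cells were put in 5 equal bins within each library.

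Sums were tested with edgeR 4.0.16 (glmQLFit and glmQLFTest, TMM scaling, filterByExpr, Benjamini-Hochberg adjustment at 0.05) in R 4.3.3. All classes with at least 20 cells in each library shared a fit, as did all mesenchymal clusters and all score bins. The library entered as a block, because the classes of a library come from the same pool of lungs. The labels call the libraries biological replicates. With the library as a block, the spread behind a p-value comes from how differences between classes or clusters vary between these 2 libraries. That variation is taken over all classes or clusters of a fit, which left 4 residual degrees of freedom. In the score trend it also takes in departures of the bins from a straight line. The method also draws the spread of each gene toward that of other genes. An SE or p-value thus does not measure the disagreement of the libraries for that gene alone. The SE of a log2 fold is its size divided by the square root of F. A mesenchymal cluster was compared with the mean of the log levels of the others, and the score trend was a slope per bin. Gene lists of at least 3 tested members were tested with camera (limma 3.58.1, preset correlation 0.01, and again with an estimated correlation), adjusted over lists within a comparison. DESeq2 1.42.0 served as an alternative. Other tools were Python 3.11.15, numpy 2.4.6, scipy 1.17.1, scikit-learn 1.9.0, igraph 0.11.9, leidenalg 0.10.2 and matplotlib 3.10.9.

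The tests, markers, gene lists, rule for named genes and most alternatives were fixed before the data were examined. The 17 lists were Hedgehog, Wnt, FGF and BMP targets, YAP and TGF-beta targets, retinoic acid pathway, Notch pathway, contractile and actin-binding genes other than the smooth muscle markers, interstitial matrix, basement membrane, G1/S, G2/M, glycolysis, cholesterol synthesis, immediate early and stress genes, secreted signals and patterning transcription factors. Genes were named by a rule. From each list it took up to 2 members with the largest absolute log2 fold among those past the threshold with the same sign in both libraries. Outside lists and markers it took the 6 largest rises and the 6 largest falls with at least 50 CPM on the higher side. Mitochondrial, ribosomal protein, haemoglobin, sex-linked and unnamed predicted genes were left out, and the text prints a part of the genes so named. Some genes that the rule took are not reported here and were not replaced by others. Markers covered epithelial, mesenchymal, mesothelial, endothelial, erythroid, macrophage, megakaryocyte, neural crest, neuronal, cardiac, hepatic, skeletal muscle, cartilage, smooth muscle and pericyte cells.

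The clustering features, the use of library scaling, the resolutions and the removal of erythroid markers were settled after the cells had been looked at. For the first clustering 3 versions were tried, and 10 for the mesenchymal one. Versions were set aside because clusters split by library, because features were noisy low-count genes or because haemoglobin led a cluster. The scoring rule that named clusters from the fixed markers was set then too.

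Fits were tested on simulated data with 200 changed genes, drawn from the real sums with a coefficient of variation of 0.07 beyond counting. In the epithelial-like comparison 45% of 2-fold and 78% of 4-fold changes were recovered among 6456 genes, and 2.38% of calls were false. For mesothelial-like cells these values were 50%, 75% and 4.58% among 6508 genes, and for endothelial-like cells 30.0%, 71% and 6.48% among 6491. Cluster M1 gave 72%, 89% and 3.59% among 7104 genes, M2 gave 77%, 96% and 3.35% among 7122, M3 gave 73%, 89% and 4.71% among 7118, and M4 gave 41%, 80% and 3.2% among 7122. The smooth muscle-like cluster gave 52%, 90% and 2.74% among 7147 genes, and the trend 49%, 97% and 4.58% among 7595, for folds between the first and the last bin. No recovered gene had the wrong sign. Cells simulated as a single population, with counting error only, were split and clustered into 3 clusters. Cell cycle regression and the removal of erythroid markers were left out there. Among 8219 genes edgeR called 0 in each of these clusters with held-out UMIs, with 3.81% to 4.44% of genes at an unadjusted p under 0.05, and at most 1 with training UMIs. With counting error only the held-out UMIs are independent of the training ones, and training UMIs gave hardly any calls either. This check could therefore not show a bias from clustering. In the fits with changed genes, many changes of 2-fold were missed.

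Alternatives were RLE in place of TMM, DESeq2's Wald test, no filter on low counts, no replicate block, only the classes compared, all UMIs in place of the held-out ones, another split, doublets kept, resolutions of 0.5 and 0.3 or 2.0 and 1.2, no cell cycle regression, 3 or 10 bins, no averaging of the score, at least 2000 UMIs, a 5% mitochondrial limit and each library left out. Remade mesenchymal clusters were matched to M1 to M4 by their overlap of cells. Free RNA was subtracted from each sum with the profile of barcodes of 10 to 100 UMIs, scaled so that all haemoglobin outside erythroid-like cells counted as free, which is an upper bound. It came to 15.0% and 36.3% of the UMIs of epithelial-like cells, 17.0% and 17.9% of mesothelial-like cells and 16.2% and 16.9% of endothelial-like cells. Further alternatives chosen after seeing the data left out smooth muscle-like cells with a transcript of 1 of 4 neural crest markers (among them Sox10, Foxd3 and Erbb3), M2 cells with a training UMI of a mesothelial marker, cluster M4, or the highest score bin, and for the trend M2 or M3.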

Results

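The series profiled single cells of the left lung lobe of CD1 mouse embryos, an outbred strain, at E11.5. At this stage the airway epithelium branches into a surrounding mesenchyme that holds the precursors of airway smooth muscle. Lobes were dissociated with dispase, a protease, and cells were captured in droplets with the 10x Genomics 3' v2 chemistry, which counts messenger RNA molecules by unique molecular identifiers (UMIs). There was 1 group of 2 biological replicate libraries, pooled from 4 and 3 lungs. The deposited matrices held 15640150 UMIs in replicate 1 and 14899093 in replicate 2. Cell calling left 892 and 1059 cells, with a median of 8950 and 7795 UMIs and 2757 and 1591 genes per cell. The series title concerns patterning of the pulmonary mesenchyme, and its design text names mesenchymal cells at stages of smooth muscle differentiation. Cell classes, mesenchymal clusters and a smooth muscle score were therefore compared within the libraries.

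Erythroid-like and mesenchymal-like cells made up most of both libraries. Mesenchymal-like cells were 49.4% of cells in replicate 1 (95% exact interval 46.1 to 52.8) and 28.0% in replicate 2 (25.4 to 30.9). Erythroid-like cells, which carry oxygen on haemoglobin, were 30.04% (27.1 to 33.2) and 54.1% (51.1 to 57.1). Among cells other than erythroid-like ones, mesenchymal-like cells were 70.7% and 61.1%, and mesothelial-like cells of the lung's outer lining 13.8% and 13.0%. Endothelial-like cells were 7.05% and 11.3% of these, epithelial-like cells 5.61% and 9.05%, and macrophage-like cells 2.88% and 5.56%. With a 5% mitochondrial limit endothelial-like cells were 3.54% and 4.09% of cells other than erythroid-like ones, and macrophage-like cells 1.69% in replicate 1. With a minimum of 2000 UMIs epithelial-like cells were 9.22% and 10.1%. The share of mesenchymal-like cells among cells other than erythroid-like ones was lower in each of these settings. It was 54.5% and 41.5% with the 5% mitochondrial limit, 51.8% and 53.1% with a minimum of 2000 UMIs and 57.6% and 51.1% with doublets kept. With 1 group there were no shares to test, and intervals covered counting error only. Haemoglobin transcripts were also found outside red cells, at 0.433% of the UMIs of mesenchymal-like cells in replicate 1 and 1.45% in replicate 2. If all of that haemoglobin was free RNA, so were up to 16.1% and 23.4% of their UMIs.

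**Figure D1:**
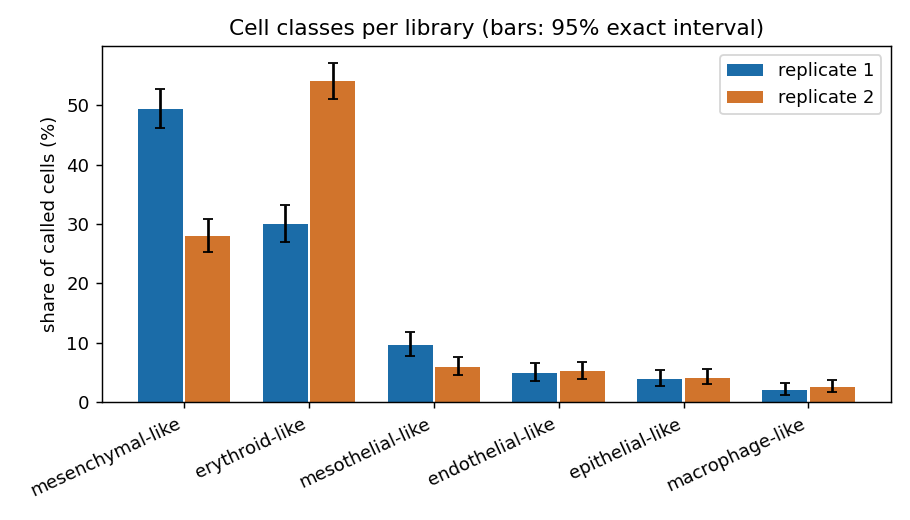
Share of called cells (%) in each class, with 1 bar per library and 95% exact intervals for counting error. Erythroid-like cells stood at 30.04% in replicate 1 and 54.1% in replicate 2, and mesenchymal-like cells at 49.4% and 28.0%.

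Classes were named from markers fixed in advance, which are not results. Epcam reached 446 ± 14.7 CPM (mean ± SD, n = 2) in epithelial-like cells, Upk3b 364 ± 27.6 CPM in mesothelial-like cells and Cdh5 728 ± 94.3 CPM in endothelial-like cells, where CPM are counts scaled to the total of each sum. Markers fixed for other cell types were also found in some classes, and their source was not tested. Myl7, a cardiomyocyte myosin light chain, led the mesothelial-like cluster at 566 ± 133 CPM, and the cartilage collagen gene Col2a1 stood at 168 ± 72.2 CPM in epithelial-like cells. The platelet genes Pf4 and Ppbp stood at 2922 ± 1108 CPM and 532 ± 481 CPM in macrophage-like cells, which numbered 18 and 27 and were not tested. Later CPM come from UMIs held out from clustering and are scaled by TMM factors unless stated. Fold changes are log2 values ± SE. Counts under alternatives are genes higher and then lower. Folds without 1 of the libraries are differences of log2(CPM + 1) in the other, with no test. Because clusters were made from expression, counts of differing genes describe those clusters, and every p-value rests on 2 libraries. The spread behind the SE and p-value of a gene was drawn toward that of other genes.

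Epithelial-like cells, the lining of the airway buds, were compared with mesenchymal-like cells to describe the tissues on either side of the airway wall. Etv5, a transcription factor induced by FGF signalling (ENSMUSG00000013089, chromosome 16, 22381309 to 22439719 in mm10), was higher by 4.56 ± 0.16, at 464 ± 3.13 against 19.9 ± 2.12 CPM (n = 2, adjusted p = 7.73e-47). The signal gene Wnt7b (ENSMUSG00000022382, chromosome 15, 85535437 to 85582473) rose to 239 ± 58.1 against 1.15 ± 1.63 CPM. Thbs1, which encodes the matrix protein thrombospondin, rose by 3.60 ± 0.17, the laminin gene Lama5 by 3.16 ± 0.30, the receptor gene Notch1 by 2.59 ± 0.40 and the immediate early gene Jun by 2.14 ± 0.22. The fibrillar collagen genes Col3a1 and Col1a1 were lower, at -3.95 ± 0.23 and -3.53 ± 0.25. The transcription factor gene Lef1, induced by Wnt signalling, was lower at -2.79 ± 0.38, and the BMP-induced gene Id3 at -1.65 ± 0.16. By edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment, 637 of 7861 genes were higher and 630 lower in epithelial-like cells. The counts were 359 and 280 with DESeq2, 1061 and 1035 with all UMIs in place of the held-out ones and 334 and 323 with free RNA subtracted. With free RNA subtracted, Etv5 stood at 5.15, Col3a1 at -6.21, Col1a1 at -4.91 and Lef1 at -4.03.

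Interstitial matrix genes were mostly lower, with 2 higher, 11 lower and 3 not passing of 16 tested (2 higher and 11 lower adjusted over the list alone). Camera gave interstitial matrix genes adjusted p = 1.85e-11, and adjusted p = 0.0382 with an estimated correlation. Patterning transcription factors were mostly lower, with 5 higher, 17 lower and 1 not passing of 23 tested (5 higher and 18 lower adjusted over the list alone). For patterning transcription factors, camera gave adjusted p = 3.39e-11, or adjusted p = 0.0264 with an estimated correlation. The transcription factor genes Irx3 and Irx5 were on the higher side, at 103 ± 8.55 against 0.460 ± 0.650 CPM and 83.3 ± 13.3 against 0.353 ± 0.174 CPM. Contractile and actin-binding genes were mostly lower, with 1 higher, 10 lower and 6 not passing of 17 tested (1 higher and 11 lower adjusted over the list alone). By camera, contractile and actin-binding genes had adjusted p = 1.72e-09 (adjusted p = 0.132 with an estimated correlation). Hedgehog targets were mostly lower, with 0 higher, 3 lower and 1 not passing of 4 tested (0 higher and 4 lower adjusted over the list alone). For Hedgehog targets, camera gave adjusted p = 0.00119, or adjusted p = 0.187 with an estimated correlation. These targets are induced in cells that receive Hedgehog signals. Notch pathway genes were mostly higher, with 3 higher, 0 lower and 2 not passing of 5 tested (3 higher and 2 lower adjusted over the list alone). By camera, Notch pathway genes had adjusted p = 0.0385 (adjusted p = 0.187 with an estimated correlation). Among 7 retinoic acid pathway genes tested, 0 were higher, 2 lower and 5 did not pass (0 higher and 4 lower adjusted over the list alone). Camera gave retinoic acid pathway genes adjusted p = 0.0417, and adjusted p = 0.187 with an estimated correlation. Median, mean and test differed in sign for the FGF target, basement membrane, glycolysis and cholesterol synthesis lists.

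Mesothelial-like cells, which cover the lung and are a source of signals to the mesenchyme beneath, were compared with the same mesenchymal-like cells. Aldh1a2, an enzyme that makes retinoic acid (ENSMUSG00000013584, chromosome 9, 71215789 to 71296243), was higher by 3.76 ± 0.15, at 379.6 ± 20.8 against 27.8 ± 2.32 CPM (n = 2, adjusted p = 1.67e-42). The signal gene Fgf9 (ENSMUSG00000021974, chromosome 14, 58070547 to 58112720) rose by 4.76 ± 0.37 to 81.3 ± 0.712 against 2.55 ± 1.59 CPM. Lama5 rose by 4.15 ± 0.22, Podxl, which encodes a sialomucin of cell surfaces, by 4.72 ± 0.19 and the integrin gene Itga3 by 4.52 ± 0.27. The transcription factor gene Gata6 rose by 1.95 ± 0.18 and the BMP-induced genes Id1 and Id4 by 1.43 ± 0.17 and 2.55 ± 0.35. Lef1 was lower at -2.00 ± 0.28, the calponin gene Cnn2 at -1.95 ± 0.19, Hoxb6 at -1.81 ± 0.24 and Cdc20, a regulator of mitotic exit, at -1.37 ± 0.23. With edgeR's quasi-likelihood test and Benjamini-Hochberg adjustment, 658 of 7861 genes were higher and 412 lower in mesothelial-like cells. The counts were 280 and 96 with DESeq2, 1012 and 743 with all UMIs in place of the held-out ones and 256 and 95 with free RNA subtracted. Without replicate 2 the fold of Fgf9 was 4.15.

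BMP targets were mostly higher, with 4 higher, 0 lower and 3 not passing of 7 tested (5 higher and 0 lower adjusted over the list alone). By camera, BMP targets had adjusted p = 2.65e-04 (adjusted p = 0.197 with an estimated correlation). Retinoic acid pathway genes were mostly higher, with 4 higher, 1 lower and 2 not passing of 7 tested (4 higher and 1 lower adjusted over the list alone). Camera gave retinoic acid pathway genes adjusted p = 0.0233, and adjusted p = 0.204 with an estimated correlation. Basement membrane genes were mostly higher, with 7 higher, 1 lower and 4 not passing of 12 tested (9 higher and 2 lower adjusted over the list alone). For basement membrane genes, camera gave adjusted p = 0.00134, or adjusted p = 0.197 with an estimated correlation. Among 29 G2/M genes tested, 0 were higher, 9 lower and 20 did not pass (0 higher and 15 lower adjusted over the list alone). Camera gave G2/M genes adjusted p = 8.56e-07, and adjusted p = 0.197 with an estimated correlation. Of 25 G1/S genes tested, 0 were higher, 9 lower and 16 did not pass, against 0 higher and 11 lower adjusted over the list alone. For G1/S genes, camera gave adjusted p = 1.17e-05, or adjusted p = 0.204 with an estimated correlation. Contractile and actin-binding genes were mostly lower, with 1 higher, 9 lower and 7 not passing of 17 tested (2 higher and 12 lower adjusted over the list alone). By camera, contractile and actin-binding genes had adjusted p = 5.98e-06 (adjusted p = 0.197 with an estimated correlation). Of 8 FGF targets tested, 1 was higher, 4 lower and 3 did not pass, against 1 higher and 4 lower adjusted over the list alone. For FGF targets, camera gave adjusted p = 0.0450, or adjusted p = 0.204 with an estimated correlation. Camera also called the Notch list lower and the secreted signal list higher (adjusted p from 0.0131 to 0.0477, against adjusted p from 0.197 to 0.204 with an estimated correlation). Median, mean and test differed in sign for the Hedgehog target, interstitial matrix and glycolysis lists.

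Endothelial-like cells, the lining of blood vessels, were compared in the same way. The basement membrane collagen genes Col4a1 (ENSMUSG00000031502, chromosome 8, 11198423 to 11312826) and Col4a2 were higher by 3.89 ± 0.15 and 4.08 ± 0.20, with Col4a1 at 605 ± 97.1 against 39.8 ± 3.19 CPM (n = 2, adjusted p = 1.85e-45). Notch1 (ENSMUSG00000026923, chromosome 2, 26457903 to 26516663) rose by 4.17 ± 0.32 to 119 ± 15.4 against 6.66 ± 0.00778 CPM, the glucose transporter gene Slc2a1 by 1.85 ± 0.30 and the ERK phosphatase gene Dusp6 by 1.60 ± 0.24. Mesenchymal-like cells held 0 held-out UMIs of the adhesion gene Icam2 and of the transcription factor gene Sox17. Against a floor of 3 counts over the group, these were at least 247-fold and 179-fold higher. The proteoglycan gene Vcan was lower at -5.17 ± 0.37, the myosin light chain gene Myl9 at -2.62 ± 0.36 and the BMP-induced gene Id2 at -2.00 ± 0.29. The edgeR quasi-likelihood test with Benjamini-Hochberg adjustment called 1010 of 7861 genes higher and 834 lower. The counts were 560 and 353 with free RNA subtracted, 674 and 318 with DESeq2 and 1495 and 1290 with all UMIs in place of the held-out ones. DESeq2 did not call Icam2 or Sox17. With free RNA subtracted, Vcan stood at -7.07, Myl9 at -4.69 and Id2 at -2.70. With another split of the UMIs, Vcan stood at -4.57. With doublets kept, Vcan stood at -6.15 and Myl9 at -2.03.

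Patterning transcription factors were mostly lower, with 1 higher, 18 lower and 4 not passing of 23 tested (1 higher and 18 lower adjusted over the list alone). By camera, patterning transcription factors had adjusted p = 6.09e-11 (adjusted p = 0.0261 with an estimated correlation). Interstitial matrix genes were mostly lower, with 1 higher, 13 lower and 2 not passing of 16 tested (1 higher and 13 lower adjusted over the list alone). Camera gave interstitial matrix genes adjusted p = 3.43e-09, and adjusted p = 0.0454 with an estimated correlation. Basement membrane genes were mostly higher, with 7 higher, 0 lower and 5 not passing of 12 tested (8 higher and 0 lower adjusted over the list alone). By camera, basement membrane genes had adjusted p = 6.34e-07 (adjusted p = 0.0851 with an estimated correlation). Notch pathway genes were mostly higher, with 4 higher, 1 lower and 0 not passing of 5 tested (4 higher and 1 lower adjusted over the list alone). Camera gave Notch pathway genes adjusted p = 0.00743, and adjusted p = 0.160 with an estimated correlation. Secreted signals were mostly lower, with 3 higher, 13 lower and 7 not passing of 23 tested (3 higher and 13 lower adjusted over the list alone). For secreted signals, camera gave adjusted p = 0.00227, or adjusted p = 0.0851 with an estimated correlation. Hedgehog targets were mostly lower, with 0 higher, 3 lower and 1 not passing of 4 tested (0 higher and 4 lower adjusted over the list alone). Camera gave Hedgehog targets adjusted p = 0.00132, and adjusted p = 0.184 with an estimated correlation. Among 6 Wnt targets tested, 0 were higher, 3 lower and 3 did not pass (0 higher and 3 lower adjusted over the list alone). For Wnt targets, camera gave adjusted p = 0.0285, or adjusted p = 0.187 with an estimated correlation. The median and the mean differed in sign for the FGF target and contractile lists.

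The 738 mesenchymal-like cells fell into 5 clusters. The smooth muscle-like cluster, named from Acta2, Actg2, Tagln, Myh11 and Cnn1, held 18.6% of them in replicate 1 and 12.1% in replicate 2. The others were numbered M1 (21.5% and 24.9%), M2 (21.8% and 22.9%), M3 (20.4% and 24.6%) and M4 (17.7% and 15.5%). None of these could be named sub-epithelial or sub-mesothelial from the markers fixed for those positions. Each was compared with the mean log level of the other 4 mesenchymal clusters, and position in the tissue was not measured. Their depth differed, from a median of 13002 and 12310 UMIs per cell in M3 to 6234 and 4718 in M4. Genes of the fixed lists were not clustering features. Scores of the G1/S and G2/M lists were regressed out before these cells were clustered, so tests of those lists between mesenchymal clusters are not independent of the clustering. Other named genes could be among the features that made the clusters. Genes that were not features were 6925 of the 7237 tested. They gave 46 of the 89 calls in M1, 251 of 383 in M2, 296 of 441 in M3 and 53 of 91 in M4. In the smooth muscle-like cluster they gave 609 of 749. The remaining calls fell on genes by which the cells had been split. A library with 0 UMIs of a gene was found for Dcx and Frem2 in the smooth muscle-like cluster and for Frem2 in M4, so their folds depend on the prior count. Emp1, Shisa2 and Ddx23 led their clusters in the UMIs used for clustering and describe them.

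**Figure D2:**
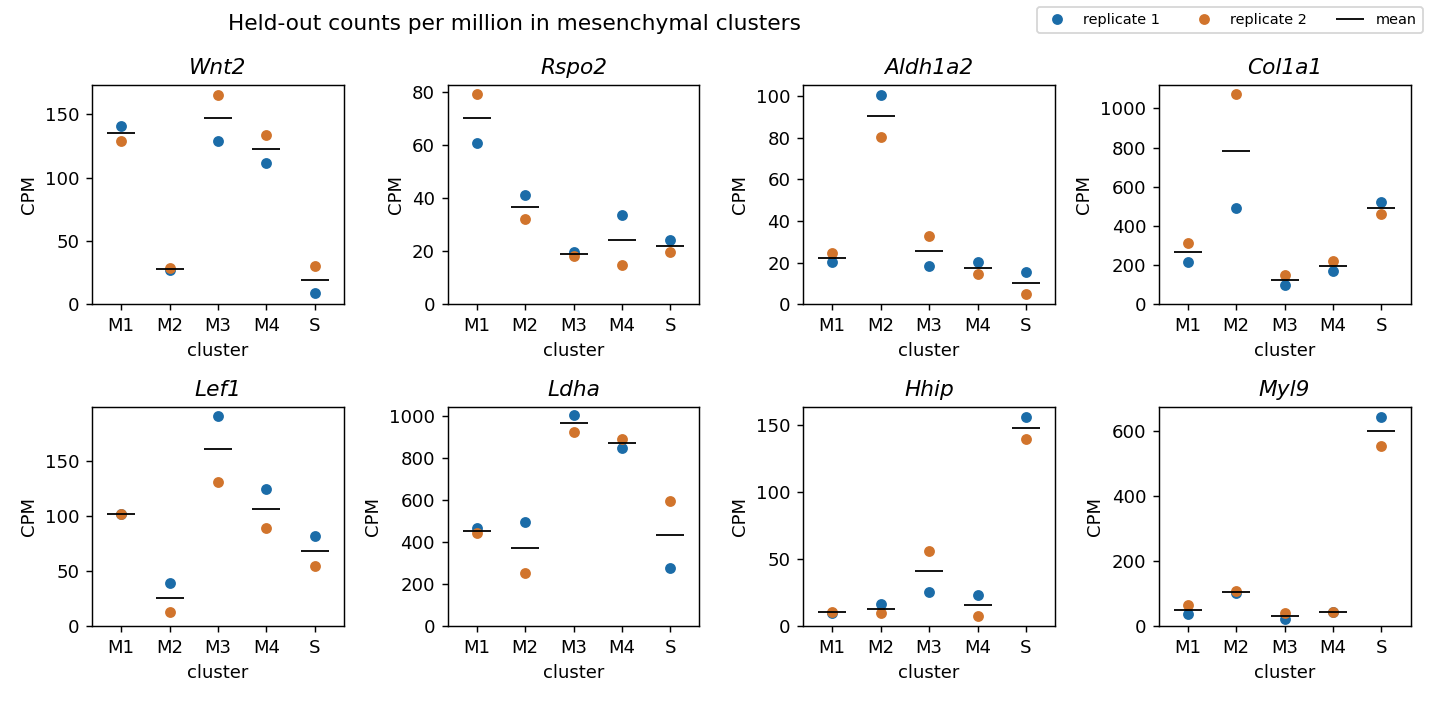
Held-out CPM (no TMM scaling) of 8 genes in mesenchymal clusters M1 to M4 and the smooth muscle-like cluster S, with 1 point per library and a line at the mean. Myl9 and Hhip stood highest in S, Aldh1a2 and Col1a1 in M2, and Rspo2 in M1, while Wnt2 was low in M2 and S.

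Cluster M1 differed from the mean of the other clusters in few genes. The signal gene Wnt2 (ENSMUSG00000010797, chromosome 6, 17988940 to 18030585) was higher by 1.4 ± 0.20 against the mean of the other clusters, at 142 ± 6.52 against 82.8 ± 15.9 CPM (n = 2, adjusted p = 6.04e-07). Wnt2 was called higher in M3 and M4 too, so it did not set M1 apart from them. Rspo2, which encodes a Wnt agonist, was higher by 1.4 ± 0.26, at 74.2 ± 15.1 against 26.5 ± 5.82 CPM. Dcx, which encodes a microtubule-binding protein, rose by 1.73 ± 0.27 and the membrane protein gene Emp1 by 1.38 ± 0.17. Vcan was lower at -0.88 ± 0.13 and the tropomyosin gene Tpm1 at -0.68 ± 0.13. The haemoglobin genes Hba-a1, Hba-a2 and Hbb-bt were among the 10 genes that led M1 in the UMIs used for clustering. Haemoglobin took 0.463% of M1 UMIs in replicate 1 and 1.98% in replicate 2, against 0.390% to 0.451% and 1.09% to 1.499% in the other mesenchymal clusters. Of 18 contractile and actin-binding genes tested, 0 were higher, 3 lower and 15 did not pass, against 0 higher and 6 lower adjusted over the list alone. By camera, contractile and actin-binding genes had adjusted p = 1.84e-05 (adjusted p = 0.263 with an estimated correlation). Among 14 secreted signals tested, 4 were higher, 1 lower and 9 did not pass (4 higher and 3 lower adjusted over the list alone). For secreted signals, camera gave adjusted p = 0.148, or adjusted p = 0.414 with an estimated correlation. Camera also called the Hedgehog target, interstitial matrix, YAP and TGF-beta target, Notch, basement membrane and immediate early lists lower and the G1/S list higher (adjusted p from 0.00204 to 0.0117, against adjusted p from 0.263 to 0.414 with an estimated correlation). The median and mean of the retinoic acid list lay below 0 and its test above. Of 7237 genes tested with edgeR's quasi-likelihood test, 42 were higher and 47 lower after Benjamini-Hochberg adjustment. The counts were 10 and 11 with DESeq2, 19 and 19 without the replicate block, 68 and 99 with all UMIs in place of the held-out ones and 116 and 146 at the lower clustering resolution. They were 70 and 65 without cluster M4, 31 and 17 at the higher clustering resolution and 58 and 20 without regression of cell cycle scores. Of the 89 calls, only 23 were shared without regression of cell cycle scores. With another split of the UMIs 41 were shared, and at the higher and the lower clustering resolution 29 and 48. DESeq2 did not call Rspo2. Without regression of cell cycle scores, Wnt2 stood at 0.07, not called, and Tpm1 stood at 0.10, with the opposite sign. The direction by camera reversed for interstitial matrix genes there and for Hedgehog targets at the lower clustering resolution, with neither list called. At the lower clustering resolution, Dcx stood at 2.36, and Rspo2 stood at 0.68, Emp1 at 0.31 and Vcan at -0.10, not called. Without replicate 1, Dcx stood at 3.18.

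Cluster M2 was rich in fibrillar matrix transcripts. Col1a1 (ENSMUSG00000001506, chromosome 11, 94936224 to 94953042) and Col1a2, which encode the chains of type I collagen, rose by 1.62 ± 0.12 and 1.34 ± 0.10, with Col1a1 at 833 ± 454 against 277 ± 30.5 CPM (n = 2, adjusted p = 2.83e-19). Aldh1a2 rose by 2.35 ± 0.25 to 95.5 ± 12.5 against 19.8 ± 0.838 CPM and the semaphorin gene Sema3d by 3.33 ± 0.38. Frem2, which encodes an extracellular matrix protein, rose by 3.04 ± 0.33 to 82.3 ± 20.9 against 8.94 ± 4.47 CPM, and the chemokine receptor gene Ackr3 by 2.82 ± 0.37 to 67.1 ± 32.5 against 8.73 ± 2.21 CPM. Looked up after these values were seen, Frem2 and Ackr3 were also higher in mesothelial-like than in mesenchymal-like cells, by 3.50 ± 0.18 and 1.91 ± 0.27, as was Aldh1a2. The mesothelial markers Upk3b and Wt1 stood at 46.1 and 42.6 CPM in M2 in replicate 1 and at 3.22 and 16.1 in replicate 2, without TMM scaling. In the other mesenchymal clusters Upk3b was at 3.49 to 13.5 and 0 to 10.9 CPM, and Wt1 at 3.37 to 8.82 and 0 to 12.7. A training UMI of a mesothelial marker was found in 15 of 96 and 2 of 68 M2 cells, against 3 to 9 cells of each other cluster in replicate 1 and 0 to 5 in replicate 2. The Hedgehog receptor and target gene Ptch1 was lower at -1.44 ± 0.18 and Wnt2 at -1.44 ± 0.29. Interstitial matrix genes were mostly higher, with 10 higher, 1 lower and 4 not passing of 15 tested (12 higher and 1 lower adjusted over the list alone). By camera, interstitial matrix genes had adjusted p = 1.14e-21 (adjusted p = 0.0232 with an estimated correlation). Among 6 Wnt targets tested, 0 were higher, 3 lower and 3 did not pass (0 higher and 4 lower adjusted over the list alone). Camera gave Wnt targets adjusted p = 1.62e-06, and adjusted p = 0.0503 with an estimated correlation. Of 4 Hedgehog targets tested, 0 were higher, 1 lower and 3 did not pass, against 0 higher and 2 lower adjusted over the list alone. By camera, Hedgehog targets had adjusted p = 1.12e-04 (adjusted p = 0.149 with an estimated correlation). Among 6 retinoic acid pathway genes tested, 2 were higher, 0 lower and 4 did not pass (4 higher and 0 lower adjusted over the list alone). Camera gave retinoic acid pathway genes adjusted p = 5.49e-04, and adjusted p = 0.106 with an estimated correlation. Of 13 glycolysis genes tested, 0 were higher, 3 lower and 10 did not pass, against 0 higher and 5 lower adjusted over the list alone. For glycolysis genes, camera gave adjusted p = 1.24e-04, or adjusted p = 0.296 with an estimated correlation. Camera also called the G1/S list lower and the BMP target, basement membrane and patterning lists higher (adjusted p from 7.35e-04 to 0.0471, against adjusted p from 0.170 to 0.328 with an estimated correlation). Median, mean and test differed in sign for the patterning, YAP and TGF-beta and G2/M lists. The edgeR quasi-likelihood test called 266 of 7237 genes higher and 117 lower after Benjamini-Hochberg adjustment. The counts were 73 and 33 with DESeq2, 159 and 72 without the replicate block, 477 and 256 with all UMIs in place of the held-out ones and 102 and 32 with another split of the UMIs. They were 169 and 85 at the lower clustering resolution, 80 and 20 at the higher clustering resolution and 546 and 378 without regression of cell cycle scores. In an alternative chosen after the data were seen, M2 cells with a mesothelial marker UMI were left out, which gave 266 and 162 and shared 295 of the 383 calls. There the BMP targets (adjusted p = 0.420) and patterning transcription factors (adjusted p = 0.124) were no longer called, and the retinoic acid pathway was (adjusted p = 0.0134). With another split of the UMIs, the matched cluster held 87 cells in place of 164. The direction by camera reversed for BMP targets there and for patterning transcription factors with no low-count filter, with neither list called. Without regression of cell cycle scores, Col1a1 stood at 2.41, and Wnt2 stood at -0.76, not called. With free RNA subtracted, Aldh1a2 stood at 3.60, Sema3d at 4.09 and Ackr3 at 3.77. With another split of the UMIs, Aldh1a2 stood at 1.52, Sema3d at 2.43 and Wnt2 at -2.74, and Frem2 stood at 1.60, not called. With doublets kept, Aldh1a2 stood at 3.24 and Frem2 at 4.76. With M2 cells holding a mesothelial transcript left out, Aldh1a2 stood at 1.67 and Ptch1 at -2.14. At the higher clustering resolution, Sema3d stood at 2.11, Frem2 at 2.09, Ackr3 at 1.65 and Ptch1 at -0.77. Without replicate 1, Frem2 stood at 4.87 and Ptch1 at -2.48.

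Cluster M3, the most deeply sampled, had more Lef1, Wnt2, Ptch1 and Ldha transcripts than the mean of the other clusters. Lef1 rose by 1.25 ± 0.16 and Wnt2 by 1.47 ± 0.19. Ptch1 rose by 0.97 ± 0.13 to 301 ± 18.7 against 172 ± 2.88 CPM (n = 2, adjusted p = 9.46e-08), and Ldha, which encodes a subunit of lactate dehydrogenase, by 0.96 ± 0.11. Shisa2 (ENSMUSG00000044461, chromosome 14, 59625308 to 59631660), which encodes a protein that retains Wnt and FGF receptors inside the cell, rose by 2.04 ± 0.19, and the chaperone gene Hspa8 by 0.55 ± 0.08. Igf1, an insulin-like growth factor gene, was lower at -2.24 ± 0.32, Col1a1 at -1.60 ± 0.15 and Myl9 at -1.80 ± 0.24. The collagen cross-linking enzyme gene Lox was lower at -2.13 ± 0.33 and the transcription factor gene Foxp2 at -1.29 ± 0.20. Glycolysis genes were mostly higher, with 9 higher, 0 lower and 4 not passing of 13 tested (11 higher and 0 lower adjusted over the list alone). Camera gave glycolysis genes adjusted p = 1.03e-12, and adjusted p = 0.102 with an estimated correlation. Of 6 Wnt targets tested, 3 were higher, 0 lower and 3 did not pass, against 4 higher and 0 lower adjusted over the list alone. For Wnt targets, camera gave adjusted p = 2.88e-05, or adjusted p = 0.0583 with an estimated correlation. Among 4 Hedgehog targets tested, 2 were higher, 0 lower and 2 did not pass (3 higher and 0 lower adjusted over the list alone). By camera, Hedgehog targets had adjusted p = 2.88e-05 (adjusted p = 0.0936 with an estimated correlation). Interstitial matrix genes were mostly lower, with 1 higher, 8 lower and 6 not passing of 15 tested (2 higher and 10 lower adjusted over the list alone). For interstitial matrix genes, camera gave adjusted p = 4.50e-14, or adjusted p = 0.0583 with an estimated correlation. Among 18 contractile and actin-binding genes tested, 0 were higher, 8 lower and 10 did not pass (0 higher and 11 lower adjusted over the list alone). By camera, contractile and actin-binding genes had adjusted p = 1.03e-12 (adjusted p = 0.0583 with an estimated correlation). Of 7 YAP and TGF-beta targets tested, 0 were higher, 2 lower and 5 did not pass, against 0 higher and 5 lower adjusted over the list alone. Camera gave YAP and TGF-beta targets adjusted p = 0.00440, and adjusted p = 0.264 with an estimated correlation. Among 25 G1/S genes tested, 5 were higher, 0 lower and 20 did not pass (8 higher and 0 lower adjusted over the list alone). By camera, G1/S genes had adjusted p = 4.66e-05 (adjusted p = 0.320 with an estimated correlation). The G2/M list was higher by camera alone (adjusted p = 0.00440, and adjusted p = 0.533 with an estimated correlation). Median, mean and test differed in sign for the immediate early, secreted signal and patterning lists. With edgeR's quasi-likelihood test and Benjamini-Hochberg adjustment, 238 of 7237 genes were higher and 203 lower. The counts were 22 and 43 with DESeq2, 106 and 102 without the replicate block and 420 and 340 with all UMIs in place of the held-out ones. They were 121 and 87 at the higher clustering resolution, 493 and 381 without regression of cell cycle scores and 388 and 311 without cluster M4. No cluster matched M3 at the lower clustering resolution, so none of its calls could be made there. DESeq2 did not call Ldha. At the higher clustering resolution, Shisa2 stood at 2.63. With free RNA subtracted, Igf1 stood at -3.14 and Myl9 at -2.74.

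Cluster M4, which had the fewest UMIs per cell, was led by genes that fall in no common list. Ddx23, which encodes an RNA helicase of the spliceosome (ENSMUSG00000003360, chromosome 15, 98645134 to 98662894), rose by 2.74 ± 0.25 to 242 ± 43.3 against 33.9 ± 22.1 CPM (n = 2, adjusted p = 6.17e-14). The endoplasmic reticulum chaperone gene Hyou1 rose by 2.11 ± 0.22 and the sterol regulator gene Insig1 by 1.54 ± 0.22. Wnt2 rose by 1.15 ± 0.27 and Ldha by 0.77 ± 0.14, while Tpm1 was lower at -0.76 ± 0.16. Of 15 interstitial matrix genes tested, 0 were higher, 3 lower and 12 did not pass, against 0 higher and 8 lower adjusted over the list alone. Camera gave interstitial matrix genes adjusted p = 7.23e-08, and adjusted p = 0.198 with an estimated correlation. Among 18 contractile and actin-binding genes tested, 0 were higher, 1 lower and 17 did not pass (0 higher and 4 lower adjusted over the list alone). For contractile and actin-binding genes, camera gave adjusted p = 2.28e-05, or adjusted p = 0.198 with an estimated correlation. Of 13 glycolysis genes tested, 2 were higher, 0 lower and 11 did not pass, against 5 higher and 1 lower adjusted over the list alone. Camera gave glycolysis genes adjusted p = 1.28e-04, and adjusted p = 0.310 with an estimated correlation. Among 15 cholesterol synthesis genes tested, 2 were higher, 0 lower and 13 did not pass (2 higher and 0 lower adjusted over the list alone). For cholesterol synthesis genes, camera gave adjusted p = 0.112, or adjusted p = 0.495 with an estimated correlation. Camera also called the FGF target, Notch and G1/S lists higher and the basement membrane, G2/M and secreted signal lists lower (adjusted p from 4.77e-04 to 0.0238, against adjusted p from 0.198 to 0.464 with an estimated correlation). The median and mean of the BMP list lay above 0 and its test below, and the median of the patterning list lay below 0 and its mean and test above. By edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment, 78 of 7237 genes were higher and 13 lower. The counts were 30 and 1 with DESeq2, 45 and 3 without the replicate block and 135 and 34 with all UMIs in place of the held-out ones. They were 202 and 120 without regression of cell cycle scores, 64 and 20 with no low-count filter and 94 and 46 at the lower clustering resolution. With doublets kept no cluster matched M4, so none of its calls could be made. Fewer cells were named mesenchymal-like there, at 40.4% and 23.5% of all cells against 49.4% and 28.0%. Which cells left the class was not looked at, so M4 cells may not have been named mesenchymal-like in that setting. DESeq2 did not call Wnt2 or Ldha. With free RNA subtracted, Ddx23 stood at 3.44. Without replicate 1, Ddx23 stood at 3.88 and Hyou1 at 2.96. With another split of the UMIs, Hyou1 stood at 1.44 and Wnt2 at 1.91. At the lower clustering resolution, Wnt2 stood at 1.83. Without regression of cell cycle scores, Tpm1 stood at -1.38.

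The smooth muscle-like cluster, compared with the mean of M1 to M4, addressed the differentiation of smooth muscle named in the design. Myl9, which encodes a regulatory myosin light chain (ENSMUSG00000067818, chromosome 2, 156775420 to 156781658), rose by 3.50 ± 0.15 to 597 ± 53.2 against 61.5 ± 11.6 CPM (n = 2, adjusted p = 2.33e-33). Igf1 (ENSMUSG00000020053, chromosome 10, 87858265 to 87937042) rose by 3.98 ± 0.17 to 469 ± 128 against 31.9 ± 4.09 CPM, the TGF-beta-induced matrix gene Tgfbi (ENSMUSG00000035493, chromosome 13, 56609523 to 56639562) by 3.29 ± 0.16 and Thbs1 by 2.51 ± 0.22. The Hedgehog target and antagonist gene Hhip (ENSMUSG00000064325, chromosome 8, 79965851 to 80058006) rose by 2.96 ± 0.26, and the immediate early genes Fos and Jun by 1.80 ± 0.42 and 1.48 ± 0.26. Notum, a Wnt target and antagonist gene, stood at 75.2 ± 6.54 CPM in the cluster, without TMM scaling, and at 12.3 ± 10.8 in M3, 3.71 ± 5.25 in M4 and 1.77 ± 2.51 in M2. No UMI of Notum was found in either library of M1 or in 1 library each of M2 and M4, so no fold is given. Wnt2 was lower at -2.59 ± 0.36, the hexokinase gene Hk2 at -1.98 ± 0.33 and Rrm2, which encodes a subunit of ribonucleotide reductase, at -0.84 ± 0.18. A neural crest marker transcript was found in 9 of 82 and 6 of 36 cells of the cluster, against 2 to 7 cells of each of M1 to M4 in replicate 1 and 0 to 6 in replicate 2. The edgeR quasi-likelihood test with Benjamini-Hochberg adjustment called 387 of 7237 genes higher and 362 lower. The counts were 161 and 68 with DESeq2, 655 and 677 with all UMIs in place of the held-out ones and 296 and 235 without the replicate block. They were 335 and 201 with another split of the UMIs and 357 and 211 with doublets kept. With free RNA subtracted, Myl9 stood at 4.23. With another split of the UMIs, Thbs1 stood at 3.36. Without replicate 1, Wnt2 stood at -1.71 and Hk2 at -0.93. Without replicate 2, Wnt2 stood at -3.23 and Hk2 at -2.81. With cells holding a neural crest transcript left out, Hk2 stood at -2.75.

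Outside the naming markers, contractile and actin-binding genes were mostly higher, with 15 higher, 0 lower and 3 not passing of 18 tested (15 higher and 0 lower adjusted over the list alone). By camera, contractile and actin-binding genes had adjusted p = 1.46e-52 (adjusted p = 0.0188 with an estimated correlation). Among 7 YAP and TGF-beta targets tested, 3 were higher, 0 lower and 4 did not pass (4 higher and 0 lower adjusted over the list alone). For YAP and TGF-beta targets, camera gave adjusted p = 2.43e-11, or adjusted p = 0.0188 with an estimated correlation. Of 4 Hedgehog targets tested, 2 were higher, 0 lower and 2 did not pass, against 3 higher and 0 lower adjusted over the list alone. By camera, Hedgehog targets had adjusted p = 3.99e-05 (adjusted p = 0.0818 with an estimated correlation). Among 6 Wnt targets tested, 2 were higher, 0 lower and 4 did not pass (3 higher and 0 lower adjusted over the list alone). Camera gave Wnt targets adjusted p = 3.98e-04, and adjusted p = 0.0818 with an estimated correlation. Of 15 interstitial matrix genes tested, 7 were higher, 0 lower and 8 did not pass, against 9 higher and 0 lower adjusted over the list alone. By camera, interstitial matrix genes had adjusted p = 7.91e-09 (adjusted p = 0.0920 with an estimated correlation). Among 14 secreted signals tested, 3 were higher, 2 lower and 9 did not pass (4 higher and 2 lower adjusted over the list alone). Camera gave secreted signals adjusted p = 0.00212, and adjusted p = 0.0818 with an estimated correlation. Of 25 G1/S genes tested, 0 were higher, 9 lower and 16 did not pass, against 0 higher and 11 lower adjusted over the list alone. For G1/S genes, camera gave adjusted p = 4.63e-06, or adjusted p = 0.355 with an estimated correlation. Among 13 glycolysis genes tested, 1 was higher, 5 lower and 7 did not pass (1 higher and 7 lower adjusted over the list alone). Camera gave glycolysis genes adjusted p = 0.00293, and adjusted p = 0.383 with an estimated correlation. Immediate early and stress genes were mostly higher, with 4 higher, 2 lower and 1 not passing of 7 tested (4 higher and 2 lower adjusted over the list alone). For immediate early and stress genes, camera gave adjusted p = 0.344, or adjusted p = 0.607 with an estimated correlation. Basement membrane genes were also called higher by camera (adjusted p = 0.0229, and adjusted p = 0.355 with an estimated correlation). Median, mean and test differed in sign for the retinoic acid and G2/M lists.

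Levels were then followed along a smooth muscle score, with the mesenchymal-like cells of each library in 5 bins of equal size. The slope per bin of Myl9 was 1.12 ± 0.10 (n = 2 libraries, adjusted p = 3.41e-10). The residual spread of this fit includes departures of the bins from a straight line within a library. Trend p-values thus do not measure differences between the libraries alone. Myl9 stood at 43.7 ± 24.1 CPM in bin 1, 84.4 ± 11.7 in bin 4 and 431 ± 47.8 in bin 5, without TMM scaling, and the slope of Igf1 was 1.29 ± 0.11. Levels of other genes differed already between bins 1 and 4. Col1a1 stood at 189 ± 18.8, 542 ± 175 and 558 ± 164 CPM in bins 1, 4 and 5 (slope 0.44 ± 0.05), and Foxp2 at 81.4 ± 5.42, 169 ± 42.8 and 176 ± 6.46 (slope 0.35 ± 0.06). Lef1 stood at 155 ± 0.454, 48.3 ± 33.1 and 59.9 ± 12.7 (slope -0.42 ± 0.06) and Ldha at 814 ± 3.26, 408 ± 159 and 441 ± 90.6 (slope -0.27 ± 0.04). Rspo1, which encodes a Wnt agonist, had a slope of 0.57 ± 0.07, the ephrin receptor gene Epha4 of 0.75 ± 0.09 and Shisa2 of -0.74 ± 0.07. Among 16 interstitial matrix genes tested, 8 were higher, 0 lower and 8 did not pass (14 higher and 1 lower adjusted over the list alone). By camera, interstitial matrix genes had adjusted p = 1.92e-18 (adjusted p = 0.0326 with an estimated correlation). Contractile and actin-binding genes were mostly higher, with 14 higher, 0 lower and 4 not passing of 18 tested (15 higher and 0 lower adjusted over the list alone). For contractile and actin-binding genes, camera gave adjusted p = 1.70e-23, or adjusted p = 0.0597 with an estimated correlation. YAP and TGF-beta targets were mostly higher, with 4 higher, 0 lower and 3 not passing of 7 tested (5 higher and 0 lower adjusted over the list alone). By camera, YAP and TGF-beta targets had adjusted p = 4.71e-05 (adjusted p = 0.0597 with an estimated correlation). Glycolysis genes were mostly lower, with 0 higher, 8 lower and 5 not passing of 13 tested (1 higher and 9 lower adjusted over the list alone). Camera gave glycolysis genes adjusted p = 1.04e-07, and adjusted p = 0.0597 with an estimated correlation. Camera also called the basement membrane list higher and the G1/S list lower (adjusted p from 0.00528 to 0.0192, against adjusted p from 0.102 to 0.715 with an estimated correlation). Median, mean and test differed in sign for the Hedgehog target, Wnt target and immediate early lists.

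By edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment, 272 of 7522 genes had a slope above 0 and 223 below. The counts were 131 and 105 with DESeq2, 507 and 475 with all UMIs in place of the held-out ones and 484 and 435 with doublets kept. Bin 5 held most smooth muscle-like cells, which made up 60 of its 88 cells in replicate 1 and 29 of 59 in replicate 2. It spanned scores of 0.0733 to 1.54 and 0.0720 to 1.52, against 0.00641 to 0.0729 and 0.00249 to 0.0709 over bins 1 to 4. Bin 4 held 15 smooth muscle-like cells of 88 in replicate 1 and 4 of 59 in replicate 2. Bins 1 to 3 held 1, 2 and 4 such cells in replicate 1 and 0, 3 and 0 in replicate 2. In an alternative chosen after the levels per bin were seen, the fit without bin 5 called 81 genes with a slope above 0 and 43 below, and shared 92 of its calls with the 495. There the slope of Myl9 was 0.43 and that of Igf1 0.58, both called. Whether the smooth muscle-like cells in bin 4 account for these slopes of Myl9 and Igf1 was not tested. They do not show a rise in cells outside that cluster. Without bin 5 the slopes of Col1a1, Foxp2, Lef1 and Ldha were 0.54, 0.37, -0.50 and -0.27, all called. The slopes of Tgfbi and Hhip, at 0.81 ± 0.10 and 0.59 ± 0.11 over all bins, were 0.03 and 0.04 and not called, and that of Thbs1, at 0.61 ± 0.11, was -0.04, below 0. Camera no longer called 2 lists without bin 5, among them the YAP and TGF-beta targets. The G1/S list reversed there, and 4 lists were newly called. The bins also held different clusters. M3 gave 44, 31, 11, 4 and 0 cells of bins 1 to 5 in replicate 1 and 33, 20, 15, 5 and 0 in replicate 2, and M2 gave 7, 8, 23, 35 and 23 cells in replicate 1 and 1, 6, 14, 28 and 19 in replicate 2. In further alternatives chosen after the data were seen, 169 and 88 genes had a slope above and below 0 without M2 and 132 and 53 without M3, of which 220 and 148 were among the 495. Without M2 the slopes of Col1a1, Foxp2, Lef1 and Ldha were 0.51, 0.33, -0.30 and -0.27, all called. Without M3 they were 0.24, 0.19, -0.20 and -0.11, and only that of Col1a1 was called. The basement membrane list was not called without M2 (adjusted p = 0.0733), nor G1/S genes without M2 (adjusted p = 0.0604) or M3 (adjusted p = 0.284). When the score was not averaged over neighbouring cells, 40 genes had a slope above 0 and 4 below. Myl9, Igf1 and Epha4 were among these, and Col1a1, Foxp2, Lef1, Ldha, Rspo1 and Shisa2 were not.

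**Figure D3:**
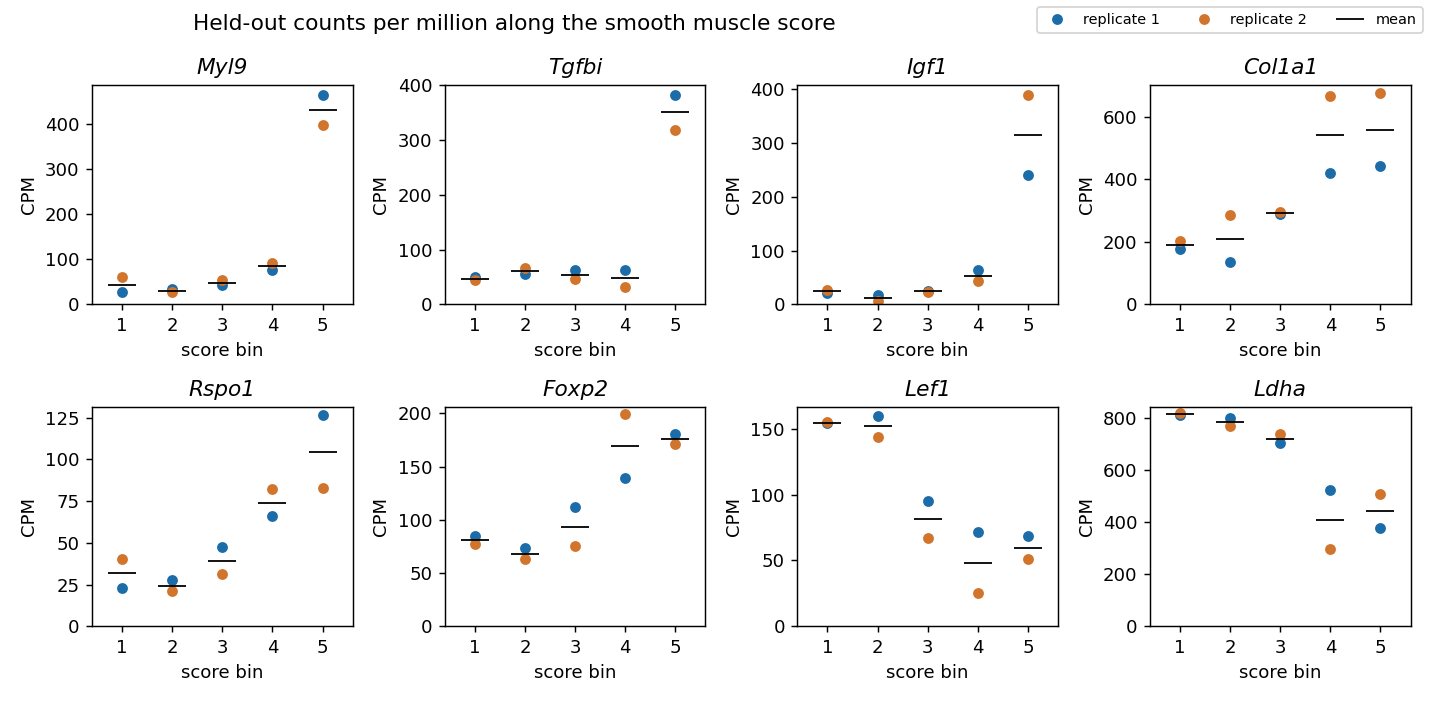
Held-out CPM (no TMM scaling) of 8 genes in 5 bins of the smooth muscle score, with 1 point per library and a line at the mean. Myl9, Tgfbi and Igf1 stood high mainly in bin 5, where Myl9 was at 431 ± 47.8 CPM against 84.4 ± 11.7 in bin 4, whereas Col1a1 and Foxp2 were already high and Lef1 and Ldha low in bin 4.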

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

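The test of the erythroid-like share at a common minimum of 2000 UMIs and the look at 8000 UMIs and at which cells with few genes were kept were chosen only after the results had been seen. Haemoglobin transcripts stood in barcodes of 10 to 100 UMIs, which hold no called cell and are in no comparison. They took 2.68% of the UMIs of 65457 such barcodes in replicate 1 and 6.22% of those of 66463 in replicate 2, above the limit that a count of 0 allows, which any free RNA passes. Macrophage-like cells numbered 18 in replicate 1 and 27 in replicate 2, and a test needed 20 in each library, so this cell class was seen but not compared with any other.

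Erythroid-like cells were 30.04% of cells in replicate 1 and 54.1% in replicate 2, and the UMI thresholds for calling a cell were 3528 and 2258. With a common minimum of 2000 UMIs the difference in share was 0.981 of the reported one, which argues against the thresholds as the cause, since that needed a ratio under 0.5 and over 0.75 was set to count against it. More cells with few genes called in replicate 2 stays open, because minima of 5000 and 8000 UMIs (ratios 1.10 and 1.05) could not decide it. At 5000 UMIs, 321 of 446 and 365 of 529 cells with fewer genes than their library's median were left. Of those left, 214 and 365 were erythroid-like. At 8000 UMIs 137 and 180 were left, of which 135 and 180 were erythroid-like, so that minimum did not part such cells from erythroid-like ones. Blood carried over with the lobes, losses in dissociation or capture, and the embryos pooled stay open too, since each library is a single pool. No biological explanation was tested, because the design has 1 group.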

How the results depend on the processing

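Alternatives chosen only after seeing the data were those without cluster M4, without the highest score bin, without smooth muscle-like cells holding a neural crest transcript and without M2 cells holding a mesothelial transcript, and the trend without M2 or M3. Counts below are genes higher and then lower, printed where they moved by over 1.5 times. Over all alternatives, named genes kept direction and call 4366 times, lost the call 519 times and reversed 9 times. These include 322 named genes with each library left out. Gene lists were labelled unchanged 1802 times, lost the call 153 times, reversed 14 times and were newly called 66 times. A list called in neither fit was labelled unchanged whatever its direction, and a reversal needed a call in at least 1 of the fits. Counts and shares stayed within 1.5 times or 1 SD of the reported value 345 times and moved 108 times. For shares this SD is that of the 2 libraries and can be wide. It was 15.1 points for mesenchymal-like cells of all cells. A mean share of 30.2% at a minimum of 2000 UMIs, against 38.7%, thus did not count as moved. No call shared between the reported fit and an alternative had the opposite sign. RLE scaling, 3 or 10 bins, fitting only the classes compared and leaving out the cells with neural crest or mesothelial transcripts moved no count by over 1.5 times. Leaving out a library gave no test. Its folds had the sign reported by construction, and each share then equals the other library's value, so these say nothing of stability. Where no cause is named below, the cause was not tested. In simulated data 72%, 77%, 73% and 41% of 2-fold changes were recovered in M1, M2, M3 and M4. M3 had the most UMIs per cell and M4 the fewest, and depth alone was not varied.

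The classes of a library are paired by their shared pool of lungs. With no replicate block the counts were 19 and 19 for M1, 159 and 72 for M2, 106 and 102 for M3, 45 and 3 for M4 and 235 lower for smooth muscle-like, and named genes lost the call 47 times with none reversed. DESeq2 called 359 and 280 for epithelial-like, 280 and 96 for mesothelial-like, 318 lower for endothelial-like, 10 and 11 for M1, 73 and 33 for M2, 22 and 43 for M3, 30 and 1 for M4, 161 and 68 for smooth muscle-like and 131 and 105 for the trend. Subtraction of free RNA left 334 and 323 for epithelial-like, 256 and 95 for mesothelial-like and 560 and 353 for endothelial-like. All UMIs in place of held-out ones, with more counts per sum and counts that also shaped the clusters, gave 1061 and 1035 for epithelial-like, 1012 and 743 for mesothelial-like, 1290 lower for endothelial-like, 68 and 99 for M1, 477 and 256 for M2, 420 and 340 for M3, 135 and 34 for M4, 655 and 677 for smooth muscle-like and 507 and 475 for the trend.

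Remade clusters hold other cells. Another random split gave 102 and 32 for M2 and 201 lower for smooth muscle-like, and the lists called were 4 for M2 in place of 9. There Mcm5 (0.035) and Rspo1 (-0.19) reversed in M2, as did BMP targets (adjusted p = 0.538, range over alternatives 0.0203 to 0.689). At the lower resolution the cluster matched to M1 held 343 cells in place of 169, no cluster matched M3, and counts were 116 and 146 for M1, 169 higher for M2 and 46 lower for M4. Smpx (0.092) reversed in M1, with Hedgehog targets (adjusted p = 0.143, range 1.52e-06 to 0.554), Wnt targets (adjusted p = 0.0405, range 9.88e-04 to 0.771) and glycolysis genes (adjusted p = 4.52e-05, range 4.52e-05 to 0.965). The higher resolution gave 17 lower for M1, 80 and 20 for M2 and 121 and 87 for M3. The lists called were 4 for M1, 5 for M2, 5 for M3 and 5 for M4, against 8, 9, 8 and 9, and G2/M genes reversed in M3 (adjusted p = 0.249, range 1.24e-06 to 0.533). With doublets kept no cluster matched M4, so neither of these pairs gave a value.

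Clusters made with cell cycle scores left in gave 20 lower for M1, 546 and 378 for M2, 493 and 381 for M3 and 202 and 120 for M4. In M1 the folds of Tpm1 (0.095), Col1a2 (0.30), Smpx (0.38) and Ddx23 (0.60) reversed. Also reversed were interstitial matrix genes in M1 (adjusted p = 0.841, range 1.21e-11 to 0.841) and G2/M genes in M2 (adjusted p = 1.93e-12, range 1.93e-12 to 0.920). Without M4, which changes what the others are compared with, there were 70 higher for M1 and 388 and 311 for M3. Dropping the low-count filter gave 20 lower for M4, and the lists called were 11 for the trend in place of 6. It reversed patterning transcription factors in M2 (adjusted p = 0.822, range 0.0111 to 0.822) and immediate early and stress genes along the trend (adjusted p = 0.0324, range 0.00760 to 0.989). Keeping doublets, with clusters remade, gave 211 lower for smooth muscle-like and 484 and 435 for the trend, and reversed Mcm5 (0.085) and G2/M genes (adjusted p = 1.44e-04, same range as above) in M2.

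The trend changed with the score and the bins used. With the score not averaged, counts were 40 and 4 for the trend, and Hedgehog targets (adjusted p = 0.0350, range 5.10e-04 to 0.866) and immediate early and stress genes (adjusted p = 0.00760, range 0.00760 to 0.989) reversed. Without the highest bin, and so with fewer bins, they were 81 and 43 for the trend, and Thbs1 (-0.040) and G1/S genes (adjusted p = 0.174, range 1.11e-12 to 0.715) reversed. Without M2 they were 169 and 88 for the trend, and without M3 132 and 53 for the trend, where Hedgehog targets reversed (adjusted p = 5.10e-04, same range as above). The lists camera called with an estimated correlation were 2 for epithelial-like, 0 for mesothelial-like, 2 for endothelial-like, 0 for M1, 1 for M2, 0 for M3, 0 for M4, 2 for smooth muscle-like and 1 for the trend, in place of 6, 9, 7, 8, 9, 8, 9, 9 and 6.

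Shares, as means of the libraries, moved with cell calling and with the clusters remade and named after it. A 5% mitochondrial limit gave 2.32% endothelial-like, 4.24% epithelial-like and 1.86% macrophage-like cells of all cells. Of cells other than erythroid-like ones it gave 3.81% endothelial-like, 48.0% mesenchymal-like and 11.6% mesothelial-like cells. A minimum of 2000 UMIs gave 4.84% endothelial-like and 5.54% epithelial-like cells of all cells, and 52.5% mesenchymal-like cells of those other than erythroid-like, against 54.4% with doublets kept and 65.9% as reported. Cells outside these classes make up the rest.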

Other observations

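The level that a sole cartilage source would leave below was chosen after the result was seen, and no other test was, but the receptor and globin genes were chosen with the values in view and are given with no test. Among receptor transcripts (held-out CPM, mean ± SD, n = 2 libraries), Fgfr2, a receptor for FGF10, stood at 150.4 ± 18.2 CPM in epithelial-like cells, 34.5 ± 10.99 in mesenchymal-like, 13.4 ± 8.68 in mesothelial-like and 8.40 ± 1.38 in endothelial-like cells, while Fgfr1 ranged from 43.0 to 70.5 over the same classes. The Wnt receptor gene Fzd2 stood at 181 ± 8.21, 157 ± 5.26 and 169 ± 0.528 CPM in epithelial-like, mesenchymal-like and mesothelial-like cells and at 16.3 ± 3.18 in endothelial-like cells. Endothelial-like cells held 701 ± 77.1 CPM of the semaphorin receptor gene Plxnd1, against 29.0 ± 2.39 in mesenchymal-like cells. Nrp1, Nrp2 and the stem cell factor gene Kitl stood at 241 ± 89.3, 205 ± 1.51 and 157 ± 9.40 CPM in endothelial-like cells and at 72.1 ± 6.88, 45.8 ± 12.2 and 7.02 ± 0.936 in mesenchymal-like cells. The BMP receptor gene Bmpr1a was at 123 ± 13.0 CPM in mesothelial-like cells and 10.3 ± 1.24 in endothelial-like cells.

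Erythroid-like cells formed 4 clusters, and Hbb-y, an embryonic beta-like globin gene, was the main beta-type globin in each of them in both libraries. It took 82.5% to 89.6% of beta-type globin UMIs, and the near-identical adult genes Hbb-bs and Hbb-bt together 7.15% to 12.5%. Hbb-bh1 took 2.45% to 6.80%, and Hba-x, the embryonic zeta globin gene, 24.1% to 41.1% of alpha-type UMIs. In cluster 2, with the most genes per cell, Hba-x took 41.1% in replicate 1 and 34.8% in replicate 2, and in cluster 3 it took 34.4% and 27.8%. Cluster 8 held 13 cells of replicate 1 and 106 of replicate 2, so it was mostly of 1 library.

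Cluster M4 was led by Ddx23 and Hyou1, and its cells had the fewest UMIs. The tables argue against free RNA as the source, since the 78 genes called higher in M4 stood at a median of 2.63 and 2.96 times their level in barcodes of 10 to 100 UMIs, where under 1 was needed and 2 or more was set against it. Loss of cytoplasm with nuclear RNA kept needed Malat1 to stand at least 1.5 times as high in M4 as in the other clusters. It stood at 0.876 and 0.780 times, under the 1.2 set against it, although the mitochondrial share was lower as this explanation predicts. That share was 3.01% and 3.78% against 3.36% and 4.10% in the other clusters together. In M3 alone it was 3.01% and 3.66%, so a low share was not particular to M4. Low depth stays open, because against cells of the other clusters matched on UMIs (78 and 46 cells each) the median ratio was 1.85 and 1.77, between the bounds of 1.5 and 2 set for and against it. These genes were called on the same UMIs, which favours higher ratios, and no biological explanation was tested.

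In the smooth muscle-like cluster Col9a1, a cartilage collagen gene, stood at 50.3 ± 0.588 CPM, against 0 in M4 and 2.10 to 7.95 in M1 to M3 (means of 2 libraries), and Fhdc1, Rab3c, Tspan18, Smoc2 and Mtcl1 were called higher there too. Cells of a cartilage progenitor kind in the cluster may be a source, and without the 20 and 4 cells holding a training UMI of Col2a1 or Acan, 0.569 and 0.855 of the Col9a1 level was left. That does not decide for Col9a1, which rested on 23 and 10 held-out UMIs. Over the other 5 genes a median of 0.877 and 0.855 was left, with Fhdc1 at 0.990 and 0.980, Smoc2 at 0.877 and 1.15, Rab3c at 1.09 and 0.658, Mtcl1 at 0.754 and 0.855 and Tspan18 at 0.519 and 0.570. Over 0.75 had been set against such cells, but the removal missed 8 of 18 and 1 of 4 cells with a held-out UMI of these markers, so a sole source would leave 0.646 (95% exact interval 0.313 to 1.01) and 0.356 (0.00899 to 1.15), which keeps this open, and no biological explanation was tested for these genes.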
